A study of Homo sapiens with 17 samples.

How the data were processed

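CUT&Tag peak lists were taken for 16 of the 17 samples, with CTCF in 9, p53 in 2 and H3K27me3 in 5. A rapamycin p53 sample was not analysed here. Per the submitters' processing notes, the tools were Bowtie 1.1.2 and MACS2 2.1.0 and the build hg38. The labels print the histone antibody as H2K27me3, while the titles give H3K27me3, which is used here. The passage of the siRNA-treated cells is not given in the sources used here. Each deposited list has 10 columns in the narrowPeak layout and came from a single library, per the peak names, so replicates were called separately. Peak names say that mitochondrial reads were removed, and those of the CTCF and p53 lists also that duplicates were removed and properly paired reads kept. Names of 5 lists (labelled early CTCF 1, rapamycin CTCF 1, both p53 lists, siH19 3) give a GRCh38.p13 reference from Ensembl, and those of the other 11 give GRCh38. Whether a control library or input was used is not stated.

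The deposited score of a peak is the whole part of 10 times its −log10 q, the deposited fold is the ratio of the pileup at the summit to the local background, and the deposited −log10 p and −log10 q are those of the authors' peak caller. A score or fold is the authors' own value for a peak and was used only to rank or describe peaks within a list. Peaks on chromosomes 1 to 22 and X were kept.

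Read totals were not given, so depth was estimated from the lists. MACS2 writes a fold of (pileup + 1) / (background + 1) and the Poisson p of the pileup, so both were solved for each peak, with the recomputed −log10 p within 0.002 of the deposited one. All solvable peaks were solved, and 97.6% to 99.99% had a single solution. The lowest background of a list is its genome-wide background per base, which scales with reads times fragment length, so relative depth is known and absolute depth is not. For the thinned lists, pileups were drawn down at random to the lowest background among lists of the antibody and the same p was asked of each. Peak edges were not called again, which is a limit of this step.

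CTCF sites were the union of all 9 lists merged at an overlap of 1 bp, and a site was present in a library with at least 1 bp under a peak. A site counted as gained when present in every library of a group and absent from every library of the other. With the replicate block the rule was looser. A site then counted when gained in at least 2 pairs of equal replicate number and lost in no pair. Gene positions came from RefSeq on GRCh38.p14 (19978 genes used). The table gives no strand, so windows were set around both ends of a gene, 1 kb for CTCF, 5 kb for p53 and 2.5 kb for H3K27me3, where starts alone had been planned. No genome sequence was used here, so no motif was searched. Expected overlap with H3K27me3 regions was measured by moving each list 10 times, in steps of 1 Mb. H3K27me3 cover was tested with limma 3.58.1 (trend) on genes covered in at least 2 libraries, with Benjamini-Hochberg adjustment at 0.05.

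Peak numbers were compared on the log2 scale with two-sided exact permutation tests. These cannot go below 0.1 for 3 against 3 or 0.2 for 3 against 2. The plan had put the latter floor at 0.1. CTCF gene lists were compared by log2 odds ratios with a pseudocount of 0.5, and H3K27me3 gene lists with camera and fry. The 19 lists hold 722 entries, of which 720 are in the reference: imprinted, senescence-associated secretory, senescence arrest, p53 target, proliferation and E2F, HOX, developmental transcription factor, let-7 target, Polycomb, CTCF and cohesin, mTOR and autophagy, fibroblast matrix, protocadherin, cardiomyocyte, endothelial, smooth muscle and pericyte, immune, epithelial and neuronal, and housekeeping genes. Fisher's exact test compared list members with other genes that could have had a gained or lost site; genes that share ends or sites are not independent.

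Named genes followed a rule: H19, IGF2, CTCF, EZH2, CDKN1A and CDKN2A always; per CTCF comparison and direction, the 6 genes near sites with the best worst-library score percentile and up to 10 list members; for H3K27me3 the 8 genes per direction with the largest change among called genes with no overlap between groups and up to 20 called list members; for p53 the 6 highest-scored peaks of each kind near genes and p53 targets with a peak. Predicted genes without a name and chromosome Y genes are not named here, and a few other genes that the rule picks are not reported here. The main tests, this rule, the gene lists and most alternatives were fixed before the data were examined. Fisher's exact tests of gene lists at gained or lost CTCF sites and at p53 peaks were not part of that plan. Alternatives fixed beforehand were the upper 50% of each list by score, equal peak number, all sequences but chromosome Y, sites joined within 500 bp, 50% overlap, other windows, centring, log2(covered bases + 250), no filter, leaving out libraries, a replicate block and, for p53, no CTCF-overlapping peaks. Those added after the data were seen are leaving out the 2 short lists (also with equal peak number or outside H3K27me3 regions), passage as in the peak names, thinning to equal background, scaling to equal mean cover and, for p53, leaving out the peaks of the 7 longer CTCF lists.

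Tested on simulated data, site counting returned all 300 gained and 200 lost of 6000 sites, the pileup solution all 4028 pileups, and the window cover all 2000 windows. For H3K27me3 in 3 against 2 libraries and 6626 genes, limma recovered 0 of 50 genes changed by 5 points, 5 of 50 changed by 10, 40 of 50 changed by 20 and 48 of 50 changed by 30, with 13 unchanged genes called. With 2 against 2, it recovered 0, 2, 28 and 47 of 50, with 2 unchanged genes called. The simulated changes were in genes with a mean cover above 10%, every SD was at least the median, and no fall shared by most genes was simulated. The counts therefore do not describe genes without cover in a whole group, which could be called at small changes (HOXA3, -4.95 points). Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.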

Results

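CUT&Tag, in which a transposase tethered to an antibody tags the DNA beside a bound protein or histone mark, was carried out on human cardiac fibroblasts. The cells were at early passage (20 to 30 population doublings), at late passage (over 50 doublings), or at late passage and kept in 1 nM rapamycin, an inhibitor of the mTOR kinase. CTCF, an insulator protein that anchors chromatin loops, was mapped in 3 libraries of each of these groups, and the transcription factor p53 in 1 early and 1 late library. The repressive histone mark H3K27me3, laid down by the Polycomb enzyme EZH2, was mapped in 3 libraries given siRNA against the long noncoding RNA H19 (siH19) and in 2 libraries labelled siNeg. The series title places these measurements in a question about H19, the microRNA let-7b and EZH2 in cellular senescence. Each library came as a list of called peaks, 16 lists in all, and no read count per library was given in the sources used here. From the fold and p of the peaks, the background was 0.232 to 0.928 fragments per base in the CTCF libraries, 0.416 and 0.663 in the p53 libraries, and 1.65 to 2.69 in the H3K27me3 libraries. Labels and files disagreed on passage: the peak names inside all 6 early and late CTCF lists carry the opposite passage to the sample labels. Replicate numbers disagreed too, with labelled early 2 and 3 numbered 1 and 2 in the peak names. These libraries are therefore called "labelled early" and "labelled late" throughout, and every difference between them has an uncertain direction. Nothing in the labels says that replicates were separate cultures. Permutation and limma p-values therefore measure only the spread between these libraries, which may be technical. Fisher's exact tests treat genes as units within fixed libraries, so their p-values hold no spread between libraries.

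CTCF peaks numbered 2971, 20934 and 28297 in the libraries labelled early, 2174, 14790 and 16699 in those labelled late, and 22592, 23940 and 27138 with rapamycin. The 2 short lists, labelled early 1 and late 1, stood apart from the other 7. Of their peaks, 17.2% and 31.6% lay in any of the 7 longer CTCF lists and 49.5% and 48.9% in the p53 lists, whereas each of the 7 longer lists had 73.8% to 88.5% of its peaks in another longer list. The short lists had a background of 0.928 and 0.595 fragments per base, above the 0.232 to 0.501 of the longer ones. The counts of gained and lost sites below are given with and without these 2 libraries, and leaving them out was decided after the data were seen.

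**Figure D1:**
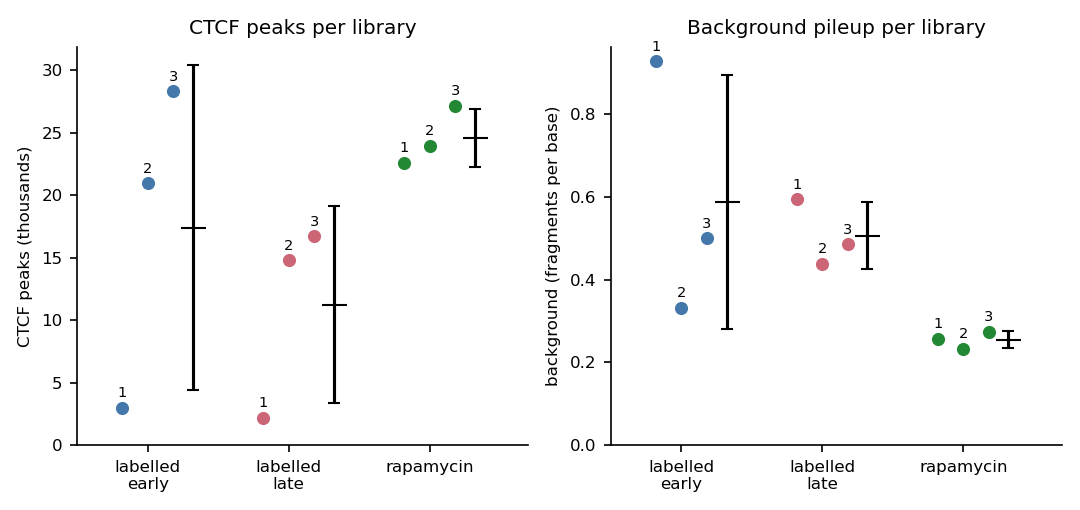
CTCF peaks per library (left) and background pileup in fragments per base (right), with points numbered by replicate and bars giving the mean ± SD of 3 libraries. The libraries labelled early 1 and late 1 have 2971 and 2174 peaks but the highest backgrounds, 0.928 and 0.595, while the rapamycin libraries have the lowest, 0.232 to 0.274.

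At the imprinted H19 and IGF2 locus, where CTCF bound between the genes keeps IGF2 from enhancers on the H19 side, all 7 longer lists had a peak just beside H19 on the side facing IGF2 (chromosome 11, 2002165 to 2003082 in the library labelled early 2, GRCh38). H19 itself spans 1995176 to 2001266. A further peak inside H19 (2000405 to 2000852 in the same library) was called in labelled early 2 and 3 and in the 3 rapamycin libraries, and in neither labelled late 2 nor late 3. Beside IGF2 (2129117 to 2149566), a peak at 2151347 to 2152577 was called in all 7 longer lists with a fold of 3.75 to 8.39 over background. The 2 short lists had no CTCF peak at either gene.

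**Figure D2:**
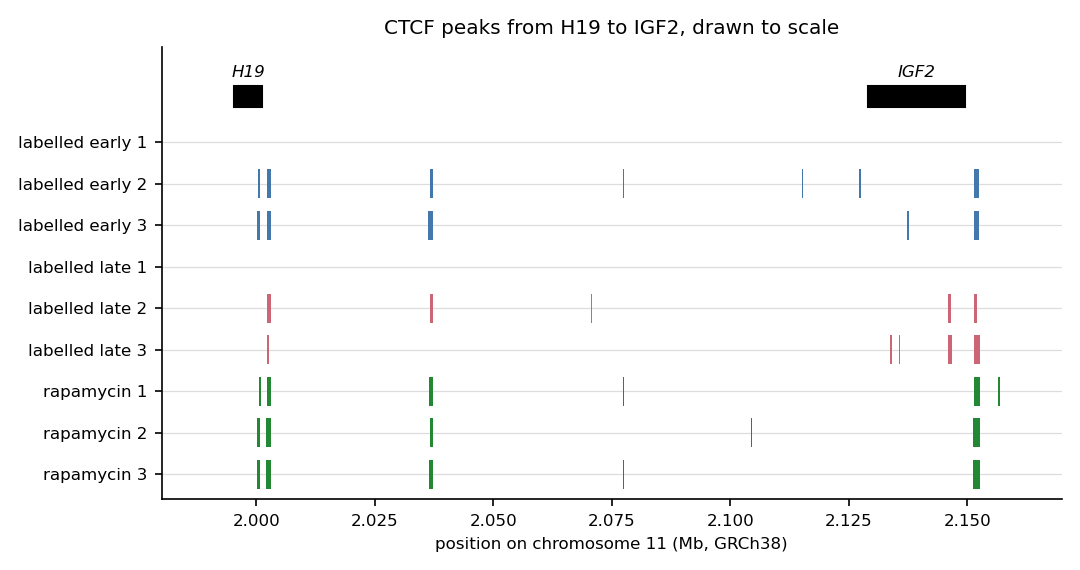
CTCF peaks (coloured boxes, to scale) of the 9 libraries along chromosome 11 between H19 and IGF2, with position in Mb on GRCh38 and the gene spans in black. Peaks beside H19 near 2002165 and beside IGF2 near 2151347 recur in 7 libraries, and labelled early 1 and late 1 have none.

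Among cell-cycle regulators, CDKN1A, encoding the cyclin-dependent kinase inhibitor p21, had a CTCF peak inside the gene (chromosome 6, 36680338 to 36680869 in labelled early 2) in labelled early 2 and 3, labelled late 2 and all 3 rapamycin libraries. CDKN2A, the gene of the senescence marker p16, had CTCF peaks in labelled early 2 and 3 and in the 3 rapamycin libraries, but none in the late-labelled libraries. It carried H3K27me3 peaks in all 5 H3K27me3 libraries. EZH2 had a CTCF peak in labelled early 3 and rapamycin 3 alone, and no H3K27me3 peak. The CTCF gene itself had a CTCF peak at its lower-coordinate end in labelled early 3, labelled late 2 and 3, and rapamycin 2 and 3.

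Passage was compared first. Without the 2 short lists, 4786 CTCF sites were present in both remaining libraries labelled early and in neither labelled late, and 1018 the other way round. The strongest early-side sites near genes lay at DAB1 and OMA1 (chromosome 1, 58546328 to 58547278), the phosphatase gene DUSP23, the ETS-family gene FEV and the forkhead gene FOXD2. Early-side sites near members of the gene lists included AKT1S1, which encodes a subunit of mTOR complex 1 (chromosome 19, 49869257 to 49870043), MCM3 and MCM7 of the replicative helicase, PML, POLR2A, the Polycomb gene EED and the cohesin loader gene MAU2. On the late side, the strongest sites were at IL17C (chromosome 16, 88638934 to 88640003), MYL12A, MYOM1 and QRFPR. Of the list members there, PHOX2A, DLX3, HAND1, ATOH1, SOX17, IRX4 and BARHL2 encode developmental transcription factors, CBX8 a Polycomb protein and TERT the catalytic subunit of telomerase. Of the 19 developmental transcription factor genes with a peak in both libraries labelled late 2 and 3, 9 had a late-side site, 47.4% against 7.14% of other genes with such peaks (Fisher's exact test on genes, adjusted p = 5.18e-05, 10 separate sites). H3K27me3 regions of the siNeg libraries held 87.0% of the 1018 late-side sites and 21.6% of the 4786 early-side sites. Of the clustered protocadherin genes with a peak in labelled early 2 and 3, all 22 had an early-side site (adjusted p = 2.47e-11, Fisher's exact test), but these rest on 2 separate sites. Cardiomyocyte genes had 3 of 3 on the late side (adjusted p = 0.00381, same test). No other list passed Fisher's exact test on either side (smallest adjusted p among them 0.231 early-side and 0.469 late-side).

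At equal peak number without the short lists, early-side and late-side sites numbered 2274 and 1608, and the 1018 late-side sites were 559 in thinned lists and 131 outside H3K27me3 regions. With all 3 libraries per group the counts were far smaller: 2 sites were present in every library labelled late and in none labelled early, and 9 the other way, with VSTM2B the only gene near a late-side site. Mean peak number was 17401 ± 13028 (SD, n = 3) for the libraries labelled early and 11221 ± 7893 (n = 3) for those labelled late, a log2 difference of -0.57 (two-sided exact permutation test, p = 0.5). Without the 2 short lists it was -0.63 (two-sided exact permutation test, p = 0.333, the smallest p that 2 against 2 can give). It changed sign without labelled late 1 (0.38) or labelled early 3 (0.04), and 3 libraries against 3 cannot give a p below 0.1. If the peak names are right, the signs in this comparison turn round (0.57, with 9 sites late-side and 2 early-side).

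Rapamycin-treated cells were compared with untreated late-passage cells, which asks what mTOR inhibition changes at the same nominal passage. In all 3 rapamycin libraries and in none of the 3 labelled late, 4943 CTCF sites were present, of which 1151 lay within 1 kb of an end of 1375 genes. They included the site at DAB1 and OMA1 again, DUSP23, the phosphatase gene SSH2 (chromosome 17, 29930921 to 29931742), the transcription factor gene RFX7 and SPMIP4. List members with such a site, 57 in all, included AKT1S1, MCM3, CENPF, PML, the cell-cycle inhibitor gene CDKN2D (chromosome 19, 10568940 to 10569550), the Polycomb gene PCGF1, HOXA10, B2M and MB. No gene list passed Fisher's exact test at these gained sites (smallest adjusted p 0.247). The opposite pattern was seen at 19 sites, among them ADGRV1, NDNF, VSTM2B and TMPRSS2, with worst-library score percentiles of 41.0, 23.2, 19.6 and 0.437. Leaving out labelled late 1 raised the sites of this opposite pattern to 1805, and the gained sites were 4967. Of genes with such a lost site, the strongest were LHX3, IL17C, DRC5, FOXD4L4, ADAMTSL1 and GSC. Besides the developmental genes below, only cardiomyocyte genes passed Fisher's exact test at lost sites, with 3 of 3 (adjusted p = 0.0234). Of the 19 developmental transcription factor genes with a peak in labelled late 2 and 3, 16 had a lost site (PHOX2A, DLX3, HAND1 and ATOH1 among them), 84.2% against 13.1% of other genes with such peaks (Fisher's exact test, adjusted p = 1.21e-10, 17 separate sites). Peaks inside siNeg H3K27me3 regions, where many of these genes lie, made up 36.7% and 43% of labelled late 2 and 3 and 10.1% to 10.7% of the rapamycin lists.

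Rapamycin libraries had 24557 ± 2335 peaks (SD, n = 3), a log2 difference to the late-labelled libraries of 1.59 (two-sided exact permutation test, p = 0.1, the smallest p that 3 against 3 can give). Without labelled late 1 the difference was 0.64 (two-sided exact permutation test, p = 0.2). At an equal number of peaks per list the gained and lost sites were 140 and 17, and without the 2 short lists as well they were 2185 and 1963. The 1805 lost sites, on which the tests of developmental and cardiomyocyte genes rest, were 742 in thinned lists and 66 outside H3K27me3 regions, and another split of the same 5 libraries gave up to 2525 (3 of 10 splits as large). If the peak names are right, the comparison is that of the next paragraph, with 1456 and 16 sites.

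Between rapamycin and the libraries labelled early, 1456 sites were present with rapamycin alone and 16 in the opposite pattern. Rapamycin-side sites lay at BCLAF3 (chromosome X, 19991119 to 19991687), TBC1D3H and TBC1D3G, PSD, RADIL and the linker histone gene H1-1. Of list members, MB, CDKN2D, HOXA10, PCDHGB2, the insulin-like growth factor binding protein gene IGFBP5, ID1, PDGFRB, VIM and FOXM1 had such a site. The sites at IGFBP5, ID1, PDGFRB, VIM and FOXM1 were weak, with worst-library score percentiles of 32.1, 19.6, 19.5, 17.4 and 9.95. No gene list passed Fisher's exact test on the rapamycin side (smallest adjusted p 0.541). FERD3L was the only gene near a site on the other side. Leaving out labelled early 1 raised the sites on that side to 1528, near FAR1, CALCA, MVD, ASXL1 and SYT8, with GSC, LHX9, ZIC4, DLX5, DLK1 and CCN2 among the list members. CDKN2D was on this side as well, at another site (chromosome 19, 10565370 to 10566046). Of the 14 developmental transcription factor genes with a peak in labelled early 2 and 3, 5 had such a site, against 4.85% of other genes with such peaks (Fisher's exact test, adjusted p = 0.00742). At equal peak number the 1456 and 16 sites became 104 and 6, and without the short lists as well 646 and 670. The 1528 sites were 656 in thinned lists and 370 outside H3K27me3 regions, and another split of the same 5 libraries gave up to 1447. The log2 difference in peak number was 1.02 (two-sided exact permutation test, p = 0.5), and 0.01 without labelled early 1.

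Gene lists fixed before the data were examined were compared by the odds, within each library, that a member has a CTCF peak within 1 kb of an end. Of 57 tests (19 lists, 3 comparisons), 0 passed an adjusted p of 0.05 and 0 an unadjusted p of 0.05 in the exact permutation test, which cannot go below 0.1 here. In the 7 longer lists, peaks were at 74.4% ± 8.01 of housekeeping genes with rapamycin (SD, n = 3), 59.6% ± 2.72 in labelled early (n = 2) and 21.2% ± 2.72 in labelled late (n = 2). For E2F and proliferation genes the percentages were 58.0, 51.0 and 21.0, for Polycomb genes 24.1, 27.8 and 9.72, and for the clustered protocadherins 42.8, 42.5 and 12.3. Over all genes the share was 30.9% to 35.4% with rapamycin, 29.2% and 33.3% in labelled early and 18.4% and 21.8% in the shorter lists labelled late. Senescence arrest genes had 59.1, 48.4 and 43.5, HOX genes 7.69, 8.97 and 14.1 ± 5.44, and cardiomyocyte genes 11.7, 7.50 and 17.5. By percent, labelled late 2 tied with labelled early 3 and rapamycin 3 for HOX genes (10.3%), and with rapamycin 1 and 3 for cardiomyocyte genes (15%). By log2 odds ratio, labelled late 2 and 3 lay above every other longer library. They had -0.83 and -0.28 against at most -1.98 for HOX genes, and -0.17 and -0.03 against at most -1.16 for cardiomyocyte genes. For developmental transcription factor genes the percentages were 7.09% with rapamycin, 18.1% ± 8.91 in labelled early and 24.8% ± 3.90 in labelled late.

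**Figure D3:**
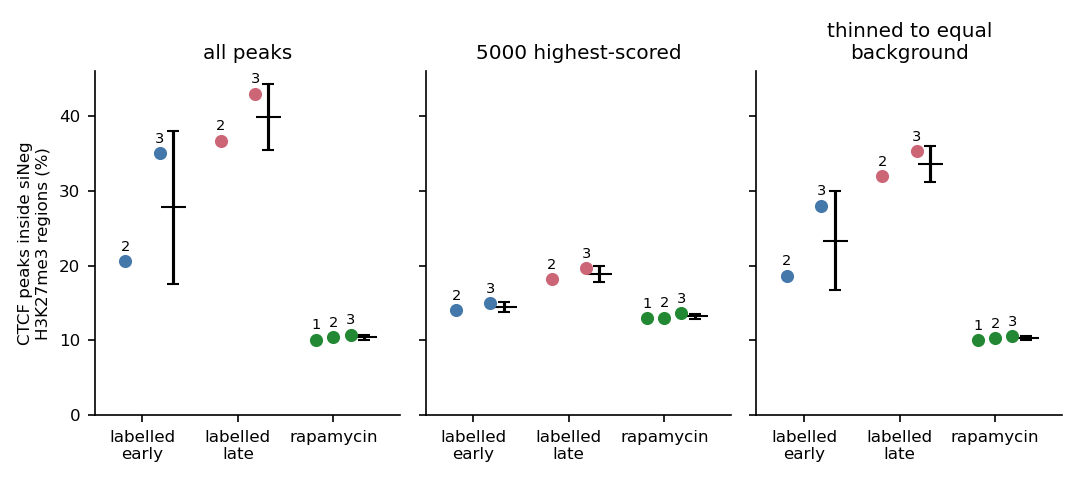
Percent of CTCF peaks that lie inside the H3K27me3 regions of the siNeg libraries, for the 7 longer lists, with points numbered by replicate and bars giving the mean ± SD (n = 2, 2 and 3). Left to right are all peaks, the 5000 highest-scored peaks of each list, and lists thinned to equal background; with all peaks the rapamycin lists sit at 10.1% to 10.7%, and labelled late 2 and 3 at 36.7% and 43%.

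H3K27me3 was compared between siH19 and siNeg to ask whether lowering H19 changes the Polycomb mark; no measurement of H19 RNA was used here. The siH19 libraries had 40121, 43586 and 46444 peaks and the siNeg libraries 88906 and 72715, a mean of 43384 ± 3166 (SD, n = 3) against 80811 ± 11449 (n = 2). Peaks covered 28.7 Mb ± 2.98 in siH19 and 59.0 Mb ± 8.91 in siNeg. On the log2 scale the differences were -0.89 for number (two-sided exact permutation test, p = 0.2) and -1.04 for covered length (same test, p = 0.2), where 0.2 is the smallest p that 3 against 2 can give. Background depth differed in the same direction, 1.65 to 1.87 fragments per base in siH19 and 2.58 to 2.69 in siNeg, a ratio of means of 1.5. With the lists thinned to equal background, an alternative added after the data were seen, the log2 differences were -0.60 for number and -0.84 for length.

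**Figure D4:**
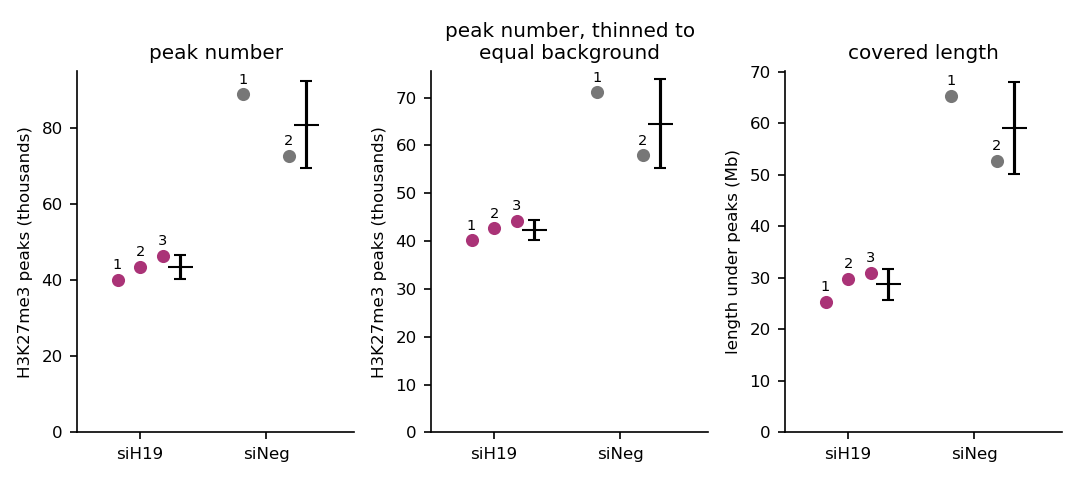
H3K27me3 peaks per library, as deposited (left) and thinned to equal background (middle), and the length under peaks in Mb (right), with points numbered by replicate and bars giving the mean ± SD (n = 3 siH19, n = 2 siNeg). As deposited, the siH19 libraries have 40121 to 46444 peaks and the siNeg libraries 72715 and 88906.

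At gene ends, H3K27me3 cover (the percent of the windows within 2.5 kb of either end that lies under peaks) fell with siH19 at 1929 of 6626 tested genes and rose at 16 (limma, adjusted p below 0.05). With lists of equal peak number 466 genes fell, and with lists thinned to equal background 1188. The median difference was -6.47 percentage points, and 92.7% of tested genes had a lower mean. Part of this share follows from the filter of 2 covered libraries. Genes covered in siNeg alone could only be lower, and those covered in siH19 alone only higher. The longer siNeg lists covered 7285 and 6443 genes, and the siH19 lists 4480 to 4862. The largest falls included the phosphate transporter gene SLC34A1 (20.0% ± 8.50 in siH19, n = 3, and 59.1% ± 5.97 in siNeg, n = 2, limma adjusted p = 0.0161), the homeobox gene GSX2 (13.3% and 48.6%) and the interleukin receptor gene IL22RA1 (0% and 33.9%). SLC32A1, BSND, IL25 and TNFRSF10C had falls of 29.8 to 30.6 points.

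Members of the lists that fell included HOXA7, HOXB13, HOXC9, HOXD10 and HOXD12, of which HOXD12 had 11.7% in siH19 and 40.8% in siNeg. The developmental regulators PAX2, PAX5, NEUROG1, NEUROG2, FOXE1, SOX14 and TLX1 fell as well, PAX2 from 30.1% to 6.93%. Imprinted DLK1 (10.9% in siH19 and 33.3% in siNeg), RTL1, MAGEL2 and DIRAS3 fell, as did the Polycomb cofactor gene AEBP2, the cell-cycle regulator gene MYBL2, HOXA3 and ABCC9. Rises were smaller and all from windows with no siNeg peak: MBD3L3 reached 13.9% ± 1.65 in siH19, and MAGEC1, ASMT, KPLCE, EXOC3L2, STYXL2, NFIA and DEFB106B reached 5.56% to 7.48%. EXOC3L2, STYXL2 and NFIA lost the rise, with a lower siH19 mean, when the whole gene body was taken. CDKN2A, with 5.08% in siH19 and 14.7% in siNeg, did not pass (limma adjusted p = 0.0634), nor did H19 (2.05% and 3.88%, adjusted p = 0.634) or IGF2 (12.4% and 20.2%, adjusted p = 0.235).

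With any single siH19 library left out, limma called 0 genes lower or higher (2395 to 2593 lower and 46 to 69 higher at an unadjusted p of 0.05, smallest adjusted p 0.0691), while all 1929 genes kept a lower siH19 mean and the median difference stayed at -6.12 to -6.65 points. Subtracting each library's mean sets the mean difference to 0 and so measures change relative to other genes: 149 genes were then lower and 334 higher (lower calls 30.8% of calls, against 99.2% in the fit of cover itself). Scaling to equal mean cover, added after the data were seen, gave the opposite balance, with 644 lower and 74 higher (lower calls 89.7%). The balance of relative changes therefore depends on the scale.

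**Figure D5:**
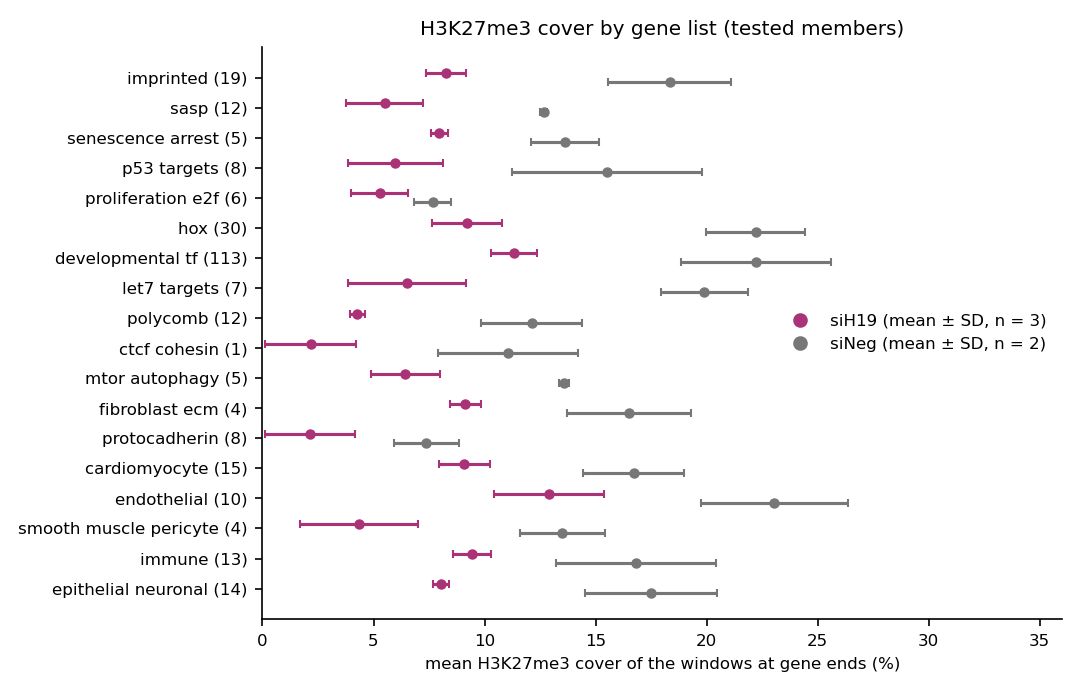
Mean H3K27me3 cover of the windows at gene ends, in percent, for the tested members of each gene list (number in brackets), with points giving the mean and bars the SD over 3 siH19 and 2 siNeg libraries. The siNeg mean is above the siH19 mean in all 18 lists, and the HOX genes are at 9.21% in siH19 and 22.2% in siNeg.

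By gene list, HOX genes showed a larger fall in percentage points than other tested genes: 16 of 30 tested members fell (21 adjusted over the list alone), with a mean of 9.21% ± 1.59 in siH19 and 22.2% ± 2.23 in siNeg (camera with its preset correlation, adjusted p = 0.0357). This call was lost with an estimated correlation (adjusted p = 0.964 with an estimated correlation) and in 4 of 5 fits with a library left out. HOX windows started from higher siNeg cover (18.3% and 15.9% over all 39 members) than all genes did (5.56% and 4.32%), from where a proportional loss gives a larger fall in points. All genes include untested ones, whereas camera compares with tested genes alone. Developmental transcription factor genes started at 22.2% and 17.7% over all 127 members and did not pass. On the log2 scale, scaled to equal mean cover or in the upper 50% of lists, 0 lists passed. The other 17 lists did not pass camera. Falls were counted in 43 of 113 developmental transcription factor genes (50 adjusted over the list alone), 8 of 19 imprinted genes (10), 7 of 12 senescence-associated secretory genes (7) and 4 of 7 let-7 target genes (7). Among epithelial and neuronal markers 4 of 14 fell (8 adjusted over the list alone), and among Polycomb genes 3 of 12 (5), p53 targets 3 of 8 (4), protocadherins 1 of 8 (4) and mTOR and autophagy genes 1 of 5 (2). Cardiomyocyte markers had 3 of 15, endothelial markers 2 of 10 (1 adjusted over the list alone), immune markers 2 of 13, smooth muscle and pericyte markers 2 of 4 and fibroblast matrix genes 2 of 4. Senescence arrest genes had 1 of 5, proliferation genes 1 of 6 and CTCF and cohesin genes 1 of 1. No housekeeping gene had cover in enough libraries to be tested, and no member of any list rose. By fry, which asks only whether a list moves on balance 1 way, 16 of 18 lists passed an adjusted p of 0.05.

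p53 was mapped in 1 library per passage, so no difference between the libraries has a replicate check. The early library had 2301 peaks and the late library 4824, a ratio of 2.1. Late peaks rested on lower pileups, with a median at the summit of 7 against 14 in the early library. The background was 0.416 fragments per base in the late and 0.663 in the early library, and the p53 lists were not thinned. Shared peaks numbered 903, 39.2% of the early list (95% Wilson interval 37.3 to 41.3) and 18.7% of the late list (17.6 to 19.8), where the intervals cover counting error only. Of the shared peaks, 89.6% also lay in the 2 short CTCF lists and 31.3% in the 7 longer ones. After p53 peaks overlapping any CTCF peak were left out, 836 early and 3326 late peaks remained and 8.37% of the early ones were shared. Of 48 p53 target genes, MDM2, whose product degrades p53, was the only member with a peak within 5 kb of an end, in the late library alone (chromosome 12, 68849695 to 68850054). That is 2.08% of the targets in the late library against 3.22% of other genes, and 0% against 1.12% in the early library. The p53 targets were therefore no more often near a p53 peak than other genes. CDKN1A and H19 had no p53 peak, and a late peak lay inside IGF2 (chromosome 11, 2148977 to 2149484). High-scored late-only peaks near genes were at ZBTB42 (chromosome 14, 104807593 to 104808328), POLE and PXMP2, MAMDC2, SLC19A1 and LUC7L, and early-only peaks included those at IGFL2 and IGFL4 and at NKX1-1 and UVSSA. Shared ones lay at DUX4 and SERINC2 and at several unnamed loci. Of the named peaks, those at ZBTB42, POLE, MAMDC2, SLC19A1, IGFL2, DUX4 and SERINC2 also overlapped a CTCF peak. Developmental transcription factor genes had an early p53 peak at 9 of 127 members, 7.09% against 1.08% of other genes (Fisher's exact test on genes within 1 library, adjusted p = 0.000255). The late library had a peak at 6 of 127, 4.72% against 3.21% (same exact test, adjusted p = 1). Of the p53 peaks, 24.9% of the early and 17.9% of the late ones lay in siNeg H3K27me3 regions, against 4.21% and 4.41% for the lists moved along the genome, and these regions cover many developmental genes.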

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

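Peaks on mitochondrial DNA, which the comparisons did not use, numbered 26 over 5 of the 16 lists, 4 to 8 in each, although the peak names say that mitochondrial reads had been removed. All 5 lists carry the Ensembl reference in their peak names, and the other 11 lists had 0 such peaks. The signal was flagged because it lies outside the main measurement. No biological explanation was tested.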

How the results depend on the processing

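Alternatives chosen after seeing the data are leaving out the 2 short lists (alone or with another choice), passage as in the peak names, thinning to equal background, scaling to equal mean cover and leaving out peaks of the 7 longer CTCF lists from p53. No p per CTCF site can be had, and the cause of each move below was not tested unless said. CTCF site counts with the replicate block follow the looser pair rule, so they differ from the main counts by definition too. Peak number is fixed by construction at equal peak number, and 50% overlap or sites joined within 500 bp do not bear on gene lists, so no value exists there.

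The CTCF peak number difference, late minus early, reversed to 0.38 and 0.04 without labelled late 1 or early 3 (range over left-out libraries -1.58 to 0.38) and to 0.57 with passage as in the peak names. Other CTCF peak number differences kept their sign, at 0.64 to 2.29 for rapamycin minus late and 0.01 to 1.72 for rapamycin minus early, in a design that cannot pass 0.05.

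Sites gained and lost, late minus early (2 and 9), were 1 and 2 in the upper 50% of lists, 7 and 0 at equal peak number, 1044 and 4822 with the replicate block, 1018 and 4786 without the 2 short lists, 1608 and 2274 when that was joined with equal number, 0 and 4 thinned, 559 and 3825 thinned without the short lists, 131 and 3703 without them outside H3K27me3 regions, and 9 and 2 by the peak names. Leaving out libraries gave 2 to 1018 gained and 9 to 4786 lost.

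Rapamycin minus late (4943 and 19) gave 2192 and 11 in the upper 50%, 140 gained at equal number, 13940 and 1880 with the replicate block, 1805 lost without the short lists, 2185 and 1963 with equal number as well, 5 lost thinned, 742 lost thinned without the short lists, 66 lost outside H3K27me3 regions, and 1456 gained by the peak names. Leaving out libraries gave 4967 to 8711 gained and 22 to 1870 lost.

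Rapamycin minus early (1456 and 16) gave 527 gained in the upper 50%, 104 and 6 at equal number, 7059 and 1690 with the replicate block, 1528 lost without the short lists, 646 and 670 with equal number as well, 8 lost thinned, 656 lost thinned without the short lists, 370 lost outside H3K27me3 regions, and 4943 gained by the peak names. Leaving out libraries gave 1461 to 4169 gained and 21 to 1743 lost.

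H3K27me3 peak number and covered length kept their sign (-0.60 to -1.04 and -0.46 to -1.19). Genes lower and higher (1929 and 16) were 466 lower at equal number, 685 and 5 with a 1 kb window, 3442 and 32 with 5 kb, 30 higher over the gene body, 9 higher in the upper 50%, 1188 lower thinned, 149 and 334 centred, 1282 and 1 with no filter (where limma warned that most residual variances are 0), 644 and 74 scaled, 87 and 185 thinned and centred, 0 and 0 at equal number and centred (510 and 692 at an unadjusted p of 0.05) and 0 and 0 with the replicate block (limma, 2455 and 46 unadjusted), which pairs only numbers 1 and 2 and so drops siH19 3, a deletion that alone gives 0 and 0. Leaving out libraries gave 0 to 2012 lower and 0 to 9 higher. With a siNeg library left out, the lone one is assumed to vary like siH19.

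Gene lists that passed camera (1) were 0 with an estimated correlation, 16 by fry, 3 centred, 0 on the log2 scale, 0 scaled, 2 at equal number, 0 in the upper 50% and 3 thinned, and 0 to 1 with libraries left out. CTCF gene lists were at 0 in all 21 alternatives, none of which could reach 0.05. Between late and early, equal replicate numbers went together only for number 1, the 2 short lists. Their deviations correlated at 0.43, against -0.18 to -0.27 for either of them with an unequal number. Numbers 2 and 3 had 0.14 and 0.07 between equal numbers, against 0.11 and 0.14 between unequal ones. Elsewhere correlations between equal numbers were near 0, so a block tests only shared numbers. These are the label numbers, and labelled early 2 and 3 are 1 and 2 in the peak names. With the block, 36 of the named H3K27me3 genes lost their call, as 36 did without siH19 3 alone, so the loss cannot be put down to the block.

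The p53 ratio (2.1) was 3.98 without CTCF-overlapping peaks and 2.43 without those of the 7 longer lists. The shared early percentage (39.2) was 60.4 in the upper 50%, 36.5 at equal number, 33.7 with reciprocal 50% overlap, 8.37 without CTCF-overlapping peaks and 35.6 without those of the 7 longer lists.

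The named H3K27me3 genes and, as 1 further item, the covered length per library made up 40 items. Of 717 comparisons of these items, 398 kept call and direction, 307 lost the call, 1 gained it and 11 reversed: NFIA (-0.536), STYXL2 (-1.54) and EXOC3L2 (-6.22) over the gene body, EXOC3L2 with 5 kb (-1.71), HOXA3 (2.16), H19 (5.28) and MYBL2 (0.650) centred, TLX1 (0.289), H19 (0.220) and IGF2 (3.00) scaled, and H19 without siNeg 1 (2.05, against -5.71 without siNeg 2). Centring adds the same 7.11 points to every gene, so the signs of HOXA3, H19 and MYBL2 there reflect that constant and no change at the gene. Named CTCF sites made up 131 entries, 1 per gene, comparison and setting, so the same site can recur among them. Of 655 comparisons of these entries, 477 kept their value and 178 moved, 114 of them at equal peak number.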

Other observations

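Written before the results they measure were the tests of peak strength and background depth for the CTCF peaks in H3K27me3 regions and of the place of the lost H3K27me3; the other tests here were chosen after the results were seen.

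CTCF sites common to all 7 longer lists numbered 6265, and 13.7% of them lay in siNeg H3K27me3 regions. Of the 4786 sites in labelled early 2 and 3 and not labelled late 2 and 3, 2273 were also in all 3 rapamycin lists and 9.90% of those lay in H3K27me3 regions, while 941 were in no rapamycin list and 64.2% of those did. Of the 1018 sites with the opposite pattern, 40 were in all 3 rapamycin lists.

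H3K27me3 peaks joined within 5 kb formed domains of 10 kb or more 162, 257 and 278 times in the siH19 libraries and 2350 and 1229 times in siNeg. After thinning to equal background these were 162, 247 and 260 against 1583 and 782. The longest domain was 24.4, 29.2 and 35.5 kb in siH19 and 60.1 and 40.7 kb in siNeg. Peaks of siH19 lay inside siNeg regions in 79.7% to 81.8% of cases, and siNeg peaks inside siH19 regions in 54.7% and 60.2%, which also follows from the longer siNeg lists.

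The 2 short CTCF lists share few sites with the other 7, and too few reads is argued against as the cause, since the lower of their backgrounds was 0.595 and the highest of the 7 longer lists 0.501. The alignment reference is argued against too, as rapamycin list 1, on the Ensembl reference, had 87.6% of its peaks in other longer lists. Little CTCF enrichment in these 2 libraries remains a candidate explanation: 24.2% of the 500 strongest sites common to the 7 longer lists had a peak in either, against 5.40% in either p53 list. Labelled late 1 carries most of this (23.6%), and labelled early 1 (6%) is close to the p53 lists (4.6% and 4.8%). A mislabelled sample was not tested, and no biological explanation was tested.

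CTCF peaks inside H3K27me3 regions were more frequent in the 4 longer early- and late-labelled lists (20.6% to 43%) than with rapamycin (10.1% to 10.7%), against 5.65% to 5.73% for the same lists moved along the genome. A deeper background is argued against as the whole cause, since after thinning the lowest share of the 4 was 1.77 times the highest rapamycin share. Among the 5000 highest-scored peaks of each list that ratio was 1.03, against 1.92 over all peaks, so weak peaks cannot be told apart from other explanations because the excess at labelled early 2 nearly vanishes while that at labelled late 3 (19.6% against 13.6%) does not. CUT&Tag background in these libraries that favours Polycomb regions may also contribute, and rapamycin or passage stays open and untested.

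H3K27me3 peaks were fewer in siH19. Depth as the whole cause is argued against, since after thinning the log2 difference was -0.60 (pooled SD 0.134), though part of the original -0.89 goes with depth. The reference of siH19 3 is argued against by -0.94 (pooled SD 0.157) without that library. A loss spread over all kinds of sequence is consistent with the share of covered length in gene spans, which differed by 0.43 points (pooled SD 0.647). Unequal enrichment between the groups would look like a biological loss and stays open, as does an effect of H19, which was untested.

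Splits of the 6 libraries show how far an arbitrary grouping of the libraries could go. For late minus early, 6 of the 10 splits gave at least the real 11 sites, and the highest other gave 1959, with both short libraries on the same side, which points to a structure of the samples. For rapamycin minus late the real 4962 sites compare with at most 272 in another split (1 of 10 as large), and for rapamycin minus early 1472 with 696 (1 of 10). Without the 2 short lists, the 1805 sites lost with rapamycin against labelled late were reached or passed in 3 of 10 splits, up to 2525, so this count cannot be told from an arbitrary grouping. The 1528 lost against labelled early compare with at most 1447, and the gained 4967 and 1461 with at most 271 and 702, where 10 splits cannot go below 0.1.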
